A study of Homo sapiens with 8 samples.

How the data were processed

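The samples were 4 established human multiple myeloma cell lines, RPMI8226, KMS12BM, KMS11 and MM.1S, each cultured for 48 h under normoxia (21% O2) and under hypoxia (1% O2). Myeloma is a cancer of plasma cells, the antibody-secreting cells of the B lineage. Each line gave 1 array per condition, 8 arrays in all, and the labels name the line and the condition of every sample. Total RNA was extracted with Trizol, labelled with Cy3 and hybridised to 1-colour Agilent human miRNA arrays following version 2.4 of the Agilent miRNA protocol, per the labels. The arrays were quantified with Agilent Feature Extraction 11.5.1.1, per the file headers. The deposited scanner files give each spot's intensity on a linear scale, as a processed signal after background subtraction and spatial detrending, with no scaling between arrays, per the file headers. They also give median spot and background intensities, a total signal per miRNA and flags for outlier, saturated and well-above-background spots. Each array held 62344 spots, of which 60180 were not controls, with 4774 probes for 2006 human miRNA entries. All names are those of the array design, so some entries carry no arm (miR-210, let-7c).

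All 8 arrays lay on 1 slide. Its first row held the 4 normoxia arrays and its second row the 4 hypoxia arrays, so slide row and condition cannot be told apart. RPMI8226, KMS12BM, KMS11 and MM.1S lay in columns 1, 2, 3 and 4 of both rows, so slide column and cell line cannot be told apart either. The authors' deposited value table holds log2 values. In each column they equalled the log2 total signal of that array minus a constant, within 0.01 for at least 99.7% of entries, and the constant lay at the array's 90.5th percentile. These constants were 3.11, 2.87, 2.64 and 2.76 for the normoxia arrays of RPMI8226, KMS12BM, KMS11 and MM.1S, and 3.71, 3.53, 2.82 and 3.94 for their hypoxia arrays. The column medians were -6.44, -6.20, -5.96 and -6.08 for normoxia and -7.03, -6.85, -6.14 and -7.26 for hypoxia, in the same order. On each array 1625 to 1687 entries held a total signal of 0.1, the value given to undetected miRNAs. The medians are therefore this fill value minus the constant and say nothing about the level of detected miRNAs. All 2027 entries of that table matched an entry of the scanner files, miRNAs were not centred, and scale and direction were thus settled. The authors' table served as an alternative with no floor set, so its fill values for undetected miRNAs entered that fit.

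For the values used here, control and outlier spots were left out, spots of a probe were averaged on the linear scale, and the probes of a miRNA (1 to 4) were averaged in the same way. Each array was then divided by its own 75th percentile over the 333 probes detected on all 8 arrays. A floor of 0.0117, the median over arrays of the lowest scaled signal among detected miRNAs, was set before taking log2, which puts the floor at -6.42. Levels below are these log2 scaled signals. A miRNA counted as detected on an array when at least 1 of its probes had at least 50% of its spots well above background. Of the 2006 miRNAs, 191 were detected on all 8 arrays, 391 on at least 1 and 1615 on none. The 286 detected on at least 4 arrays were tested, and 77 of their values lay at the floor. Under this scaling a miRNA "rose" or "fell" relative to the 75th percentile of its array.

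Hypoxia was compared with normoxia by limma (lmFit and eBayes, two-sided, no trend, not robust) with the cell line as a block and the condition as the tested term. Benjamini-Hochberg adjustment ran over the 286 miRNAs, with a threshold of 0.05. The pairing came from the cell line named in the labels, while the replicate numbers 1 to 4 follow accession order and stand for RPMI8226, KMS12BM, KMS11 and MM.1S in both groups. Deviations from the group means correlated within lines at r = 0.90, 0.96, 0.95 and 0.91 across miRNAs, against at most -0.13 between lines, and across miRNAs the values are not independent. Such deviations cancel out over the 4 lines of a group, which by itself pushes the values between lines below those within. Each line was also compared with the mean of the other 3, with condition in the model and adjustment over all miRNAs and the 4 contrasts together. Nothing in the labels names separate cultures within a line and condition, so the hypoxia test measures the spread of the response between 4 lines, with 1 culture each. The line contrasts rest on the normoxia and hypoxia arrays of a line as its 2 samples. Whether the response differed between lines leaves no residual degrees of freedom, so differences within 1 line are values with no test. Detection and signal were compared by exact sign-flip permutation over the 4 lines, two-sided, whose smallest possible p is 0.125 (2 of 16 sign patterns).

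A miRNA detected on no array of a line or condition has only a bound there. The bound is the brighter group's mean against, per array of the dim group, the higher of the lowest signal among the detected probes of that array (log2 -5.56 to -4.30) and the miRNA's own signal, averaged as log2 values. Where a miRNA was undetected in 1 or more of the other 3 lines, their values at or near the floor entered the mean of the others, so such differences depend on the floor. The named miRNAs follow a rule. For hypoxia it takes miR-210, and up to 12 with the largest rise and 12 with the largest fall among those past the threshold that moved the same way in all 4 lines. For each list it takes up to 4 members with the largest difference. For each line it takes the 4 largest excesses and 2 largest deficits past the threshold, and the 3 largest rises and 3 largest falls under hypoxia among miRNAs detected on both arrays of the line. A miRNA named outside the rule is said to be chosen after its values were seen.

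The lists were miRNAs described as raised by hypoxia, miRNAs described as lowered by hypoxia, the miR-17 family (the miR-17 cluster and its paralogous clusters, where, as in each list, entries with a locus suffix such as miR-19b-1-5p were not matched), the let-7, miR-15/16, miR-29 and miR-30 families, the miR-23/27/24 clusters, p53-responsive miRNAs, lymphoid oncogenic miRNAs, B-lineage miRNAs, the imprinted DLK1-DIO3 cluster, the placental cluster C19MC, and entries for GC-rich miRNAs taken as a sign of RNA or labelling quality. Markers of erythroid, myeloid, liver, stromal and endothelial, epithelial, muscle and neural cells stood for RNA from other cells or serum. Lists share members (miR-20a and miR-20b lie in both the miR-17 family and the hypoxia-lowered list). Lists with at least 3 tested members were tested with camera (preset correlation 0.01), which compares a list with all other miRNAs, and beside it with an estimated correlation and with fry, which asks whether the members move one way. Adjustment ran over the lists. The samples, groups, tests, lists, naming rule and alternatives were fixed before the data were examined, except where said otherwise.

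The alternatives were other scalings (75th percentile of all probes, quantile, none), normexp background correction, other probe summaries, the authors' value table, other detection filters and floors, eBayes with a trend or robust, no replicate block, and leaving out each line or array. The scanner files used here hold no mean spot signal, so normexp (offset 50) ran on median signals. The 75th percentile of all probes was a raw signal of 1.16 to 2.34, near the SD of the negative controls (1.82 to 2.32), so that alternative scales to background. Scaling by the median of the 333 probes and by the 2 labelling spike-in RNAs was added after the data were seen. No spot was flagged saturated and there was 1 slide, so those alternatives changed nothing and were not run. All 8 sample columns of the authors' table were mapped, and 0 columns stayed unmapped.

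The number of arrays limits the precision. The standard error of the hypoxia difference had a median of 0.12 on the log2 scale over the 286 miRNAs, with 3 residual and 3.71 prior degrees of freedom. The steps were tested on simulated data with the spread of the real values (20 simulations, 286 miRNAs, 60 of them changed). Hypoxia differences of 0.5, 1 and 2 on the log2 scale were recovered in 65%, 98% and 100% of cases, with 4.10% false among the calls. For 1 line against the others the shares were 30.8%, 91.2% and 99%, with 2.10% false. A list of 13 members shifted by -0.5 was recovered in 100% of simulations, and 2.22% of unchanged lists were called. The simulated miRNAs were independent of each other, while the real miR-17 family had an estimated correlation of 0.668. The 2 list shares therefore do not hold for lists whose members move together. The simulations also started from scaled values, with no error in the scaling and no floor. In the line simulation only 1 line was shifted. The recovered shares and the false shares of 4.10% and 2.10% thus do not cover errors from the scaling or the floor. Spot values were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and models were fitted with R 4.3.3 and limma 3.58.1. No coordinates are given, since the gene table at hand (assembly GRCh38.p14) and the build named in the file headers differ. That table served only to find which miRNA genes neighbour each other.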

Results

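miRNA levels were measured on 8 single-colour arrays from 4 human myeloma cell lines, RPMI8226, KMS12BM, KMS11 and MM.1S, each kept for 48 h at 21% or 1% O2. There were 4 normoxia and 4 hypoxia arrays, 1 of each per line. On the normoxia arrays 271, 265, 266 and 262 miRNAs were detected in RPMI8226, KMS12BM, KMS11 and MM.1S, and on the hypoxia arrays 303, 314, 247 and 324. The mean was 266 ± 3.74 (SD, n = 4) under normoxia and 297 ± 34.4 under hypoxia. The difference of 31 ± 35.5 was positive in 3 of 4 lines and did not pass the exact sign-flip permutation test (p = 0.25, smallest possible 0.125). KMS11 was the only line with fewer detected miRNAs under hypoxia. By Feature Extraction's own detection flag KMS11 had 1 more, and the number was higher in 4 of 4 lines (exact sign-flip permutation p = 0.125).

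Before scaling, the 75th percentile of the commonly detected probes was higher under hypoxia in 4 of 4 lines. On the log2 scale it was 8.05 ± 0.31 under normoxia and 8.54 ± 0.33 under hypoxia (SD, n = 4). The difference was 0.49 ± 0.28 (exact sign-flip permutation p = 0.125, the smallest this design can give). The 10 brightest miRNA entries held 86.3% ± 0.963 of the summed signal under normoxia and 82.7% ± 1.75 under hypoxia, lower in 4 of 4 lines (exact p = 0.125). The log2 summed signal differed by 0.04 ± 0.12 (exact p = 0.625). Arrays of the same line resembled each other most, with r of 0.982 to 0.986 across miRNAs between normoxia and hypoxia, against at most 0.919 between lines.

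The series' design text asks which miRNAs change when myeloma cells are cultured under hypoxia. miR-210, the classic miRNA target of the hypoxia-inducible factors, rose 4.32-fold (log2 difference 2.11, SE 0.23, adjusted p = 0.00629) and was higher in 4 of 4 lines. miR-7-5p, described as a tumour suppressor that targets growth factor signalling, fell 2.45-fold (log2 difference -1.29, SE 0.13, adjusted p = 0.00629), also in 4 of 4 lines. It was detected on 4 normoxia and 3 hypoxia arrays, so its fold rests in part on an undetected value. Its lowest level was -5.95, in KMS12BM under hypoxia. miRNAs of the miR-17 family, which MYC drives and which promote proliferation, were lower after scaling, and 12 of the 13 tested members of the list fell. As a list they passed the camera test (adjusted p = 1.62e-06) but not with an estimated correlation (adjusted p = 0.872 with an estimated correlation) or with fry (adjusted p = 0.0539). No member was called without scaling, with the labelling spike-ins, the 75th percentile of all probes or the authors' table, or without the block. The camera test with the preset correlation passed in these 5 settings (adjusted p from 1.73e-07 to 0.0102). It compares the list with all other miRNAs, so a change of a single factor per array leaves it nearly as it was. Its passing without scaling, with the spike-ins and with all probes is therefore no separate support. miR-378a-3p, hosted in the metabolic coactivator gene PPARGC1B, fell by 0.83 on the log2 scale (SE 0.14), and miR-378i, an entry of the same family, fell by 0.92 (SE 0.12). Whether these entries share signal was not tested, so their falls may not be separate.

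In all, 9 miRNAs rose, 46 fell and 231 did not pass the threshold of limma with Benjamini-Hochberg adjustment, and each of the 55 moved the same way in all 4 lines. At an unadjusted p under 0.05 there were 21 higher and 72 lower. The rises spanned 1.25-fold to 4.32-fold and the falls 1.27-fold to 2.45-fold. After miR-210, the rises were miR-3960 (0.61 on the log2 scale), miR-4634 (0.58), miR-6090 (0.50), miR-135a-3p (0.47), miR-3940-5p (0.42), miR-4739 (0.41), miR-6089 (0.36) and miR-4433-3p (0.33), with standard errors of 0.09 to 0.16 and adjusted p from 0.0294 to 0.0492. miR-135a-3p was detected on 1 normoxia array and 4 hypoxia arrays, and its KMS11 normoxia level of -6.26 was near the floor. Its mean hypoxia level of -5.26 lay below the lowest detected probe of each normoxia array (-4.91 to -4.30), so the size of its rise is uncertain. miR-4634 was detected on 2 normoxia and 3 hypoxia arrays. In KMS11 miR-3940-5p differed by 0.74, against 0.28 to 0.34 in the other lines. The largest falls after miR-7-5p were those of miR-4284 (-0.94), miR-378i, miR-18a-5p (-0.91), miR-18b-5p (-0.87), miR-378a-3p, miR-17-3p (-0.82), miR-16-2-3p (-0.81), miR-20a-3p (-0.73), miR-17-5p (-0.64), miR-6085 (-0.57) and miR-19a-3p (-0.57). Their standard errors lay between 0.09 and 0.17 and their adjusted p between 0.00629 and 0.0206.

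**Figure D1:**
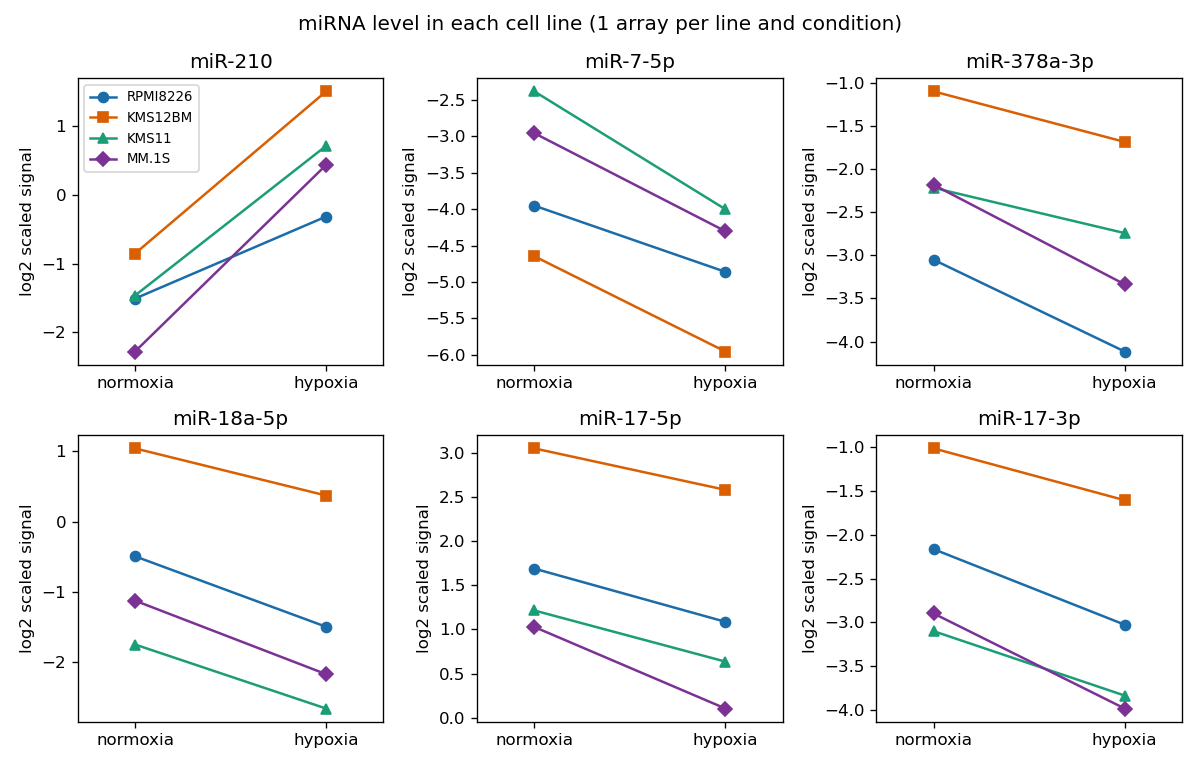
Level of 6 miRNAs (log2 scaled signal, vertical axis) under normoxia and hypoxia, with 1 point per array and a line joining both arrays of a cell line. miR-210 rose in 4 of 4 lines, by 1.19 in RPMI8226 up to 2.72 in MM.1S, and the other 5 fell in 4 of 4 lines after scaling.

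How many miRNAs rose or fell depended on the scaling of the arrays. The median difference of the 286 tested miRNAs was -0.12 with the scaling used and 0.35 with none. Without scaling 83 were higher and 1 was lower (miR-7-5p), so that the lower share of the calls went from 83.6% to 1.19%. It was 0.649% after scaling to the labelling spike-ins (153 higher, 1 lower), 0% with the 75th percentile of all probes (2 higher, 0 lower), 68.1% with the median of the common probes (15 higher, 32 lower), 75% with quantile scaling (3 higher, 9 lower) and 56% with normexp (11 higher, 14 lower). All 9 that rose were higher in 4 of 4 lines without scaling too. This had to follow, since the scaling factor was higher under hypoxia in 4 of 4 lines and leaving it out raises every difference. Of the 46 that fell, 9 were lower in 4 of 4 lines without scaling, 24 had a mean below 0, and 37 had a mean within 0.2 of 0. The 9 were miR-7-5p, miR-4284, miR-378i, miR-18a-5p, miR-18b-5p, miR-378a-3p, miR-17-3p, miR-16-2-3p and miR-17-5p. Scaling by a single factor per array leaves the order of the differences in a line as it is. With quantile scaling and with normexp, which do not, 43 and 45 of the 46 lay below the median of the tested miRNAs, and 9 of the 9 rises above it.

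**Figure D2:**
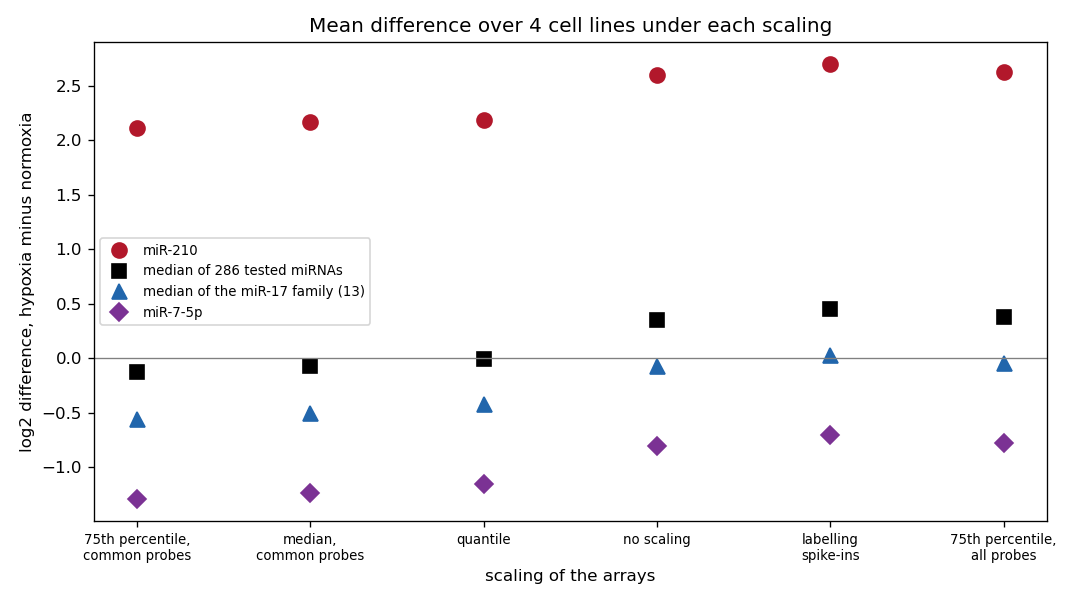
Mean log2 difference between hypoxia and normoxia over 4 cell lines (vertical axis) under 6 scalings of the arrays (horizontal axis) for miR-210, miR-7-5p, the median of 286 tested miRNAs and the median of the 13 tested members of the miR-17 family. The family's median turned from -0.56 with the scaling used to -0.07 with none and 0.03 with the labelling spike-ins.

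No single line carried miR-210 or miR-7-5p, but the counts leaned on each line. Without RPMI8226 there were 4 higher and 36 lower, without KMS12BM 1 and 6, without KMS11 2 and 15, and without MM.1S 1 and 7. Without the cell line as a block 0 miRNAs passed (limma, 1 higher and 2 lower at an unadjusted p under 0.05), and none passed with the authors' value table (26 higher and 55 lower at an unadjusted p under 0.05, with the fill values of undetected miRNAs left in). miR-210 kept a difference of 1.63 to 2.70 under every alternative and lost its call under these last 2 (adjusted p = 0.368 without the block, 0.0545 with the authors' table). miR-7-5p missed the threshold there with its difference kept (-1.29 without the block, -1.28 with the authors' table), and also with normexp (-0.30, adjusted p = 0.116) and with the 75th percentile of all probes (-0.78, adjusted p = 0.343). With the mean of log2 values miR-7-5p passed with a smaller difference (-0.74).

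The miR-17 family had 13 tested members in its list, each lower in 4 of 4 lines with the scaling used. Of these, 12 fell over all tested miRNAs and 13 adjusted over the list alone, with a median of -0.56. Examples were miR-18a-5p (-0.91), miR-18b-5p (-0.87), miR-17-3p (-0.82) and miR-20a-3p (-0.73), and miR-106b-5p, at -0.31 (adjusted p = 0.12), was the list member that did not pass over all tested miRNAs. A further tested arm of the miR-17 cluster, miR-19b-1-5p, is outside the list, as entries with a locus suffix were not matched. It was lower in 2 of 4 lines (-1.44 in KMS12BM and -0.16 in KMS11) and did not pass either (-0.40, limma adjusted p = 0.30). In RPMI8226 and MM.1S both values lay at the floor, so no difference could be seen there. It was detected on 3 normoxia arrays and 1 hypoxia array. The number of called members was 10 without RPMI8226, 4 without KMS12BM, 6 without KMS11 and 4 without MM.1S.

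Of the 6 tested members of the list described as lowered by hypoxia, 3 fell (miR-20a-3p, miR-20a-5p and miR-20b-5p, all also members of the miR-17 family) and 5 fell adjusted over the list alone. Its median was -0.55 (camera adjusted p = 0.0284, adjusted p = 0.872 with an estimated correlation, fry adjusted p = 0.0612). Of the 14 tested members of the list described as raised by hypoxia, miR-210 rose, and it was also the only 1 adjusted over the list alone. The others ranged from -0.19 (miR-103a-3p) to 0.22 (miR-26a-5p). Its median of -0.02 and its mean of 0.13 differed in sign, and the camera test, directed up, did not pass (adjusted p = 0.223). It passed without scaling and with the 75th percentile of all probes (adjusted p = 0.0241 and 0.0216), but not with the scaling used and an estimated correlation (adjusted p = 0.892 with an estimated correlation) or with fry (adjusted p = 0.89). The list of GC-rich entries, a sign of RNA or labelling quality, stood above the other miRNAs, with a median of 0.08 over 19 tested members (camera adjusted p = 0.0282, adjusted p = 0.727 with an estimated correlation, fry adjusted p = 0.246). Among them 1 member rose (miR-3960) and 0 did adjusted over the list alone, while miR-4281 (0.44), miR-1915-3p (0.38) and miR-3196 (-0.33) did not pass. The list was fixed by name, and the GC content of the other miRNAs that rose was not examined.

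In the remaining lists few members passed. miR-142-3p, a haematopoietic miRNA, fell by 0.44 on the log2 scale (adjusted p = 0.0457), 1 of 8 tested B-lineage miRNAs, with 0 adjusted over the list alone. miR-487b of the DLK1-DIO3 cluster fell by 0.46 (adjusted p = 0.0492), 1 of 3 tested members, and adjusted over the list alone 1 rose (miR-134) and 1 fell. Both differences turned positive without scaling, with the 75th percentile of all probes and with the spike-ins. No member passed, over all tested miRNAs or adjusted over the list alone, among the let-7 family (8 tested, median -0.14), the miR-15/16 family (6, -0.16), the miR-23/27/24 clusters (5, -0.11), the miR-29 family (4, 0.02), the miR-30 family (4, -0.02), the p53-responsive miRNAs (3, 0.21) and the lymphoid oncogenic miRNAs (11, -0.03). The camera tests of these lists, of the B-lineage list and of the DLK1-DIO3 cluster did not pass, with adjusted p from 0.223 to 0.996. Median, mean and test differed in sign for the miR-23/27/24 clusters (camera up), the miR-29 family (mean -0.01), the miR-30 family (camera up), the lymphoid list (camera up, fry down) and the DLK1-DIO3 cluster (median -0.35, camera up). Examples were miR-34a-5p (0.27, adjusted p = 0.202), miR-221-3p (-0.50, adjusted p = 0.0581), miR-15b-3p (-0.53, adjusted p = 0.101) and miR-155-5p (0.15, adjusted p = 0.561), the last with 0.81 in RPMI8226 and -0.10 to 0.00 in the other lines.

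Most markers of other cell types were not detected, while some neural, stromal and endothelial entries were. None of the 42 entries of the placental cluster C19MC, the 5 erythroid, the 2 liver or the 4 muscle entries was detected on any array. The myeloid miR-223-3p was detected on 1 array, the epithelial miR-205-3p on 2, and the stromal miR-199a-3p and miR-199b-5p on 2 each. Of the stromal and endothelial entries 1 was tested, miR-126-3p (0.10, adjusted p = 0.478), which was detected on 6 arrays with a level of -3.53 in KMS12BM. The 3 tested neural entries were miR-128 (-0.34), miR-9-5p (-0.19) and miR-9-3p (-0.17), of which 0 passed (camera adjusted p = 0.558). miR-128 was detected on 8 of 8 arrays, with a level of -2.99 in KMS12BM, miR-9-5p on 7 and miR-9-3p on 5.

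Within single lines, miR-210 had the largest rise under hypoxia in each of the 4, by 1.19 in RPMI8226, 2.36 in KMS12BM, 2.18 in KMS11 and 2.72 in MM.1S. There was 1 array per line and condition, so these differences have no test, and neither has their contrast between lines. Among miRNAs detected on both arrays of a line, a difference over 2-fold was seen for 1 higher and 4 lower of 261 in RPMI8226, 4 and 2 of 259 in KMS12BM, 1 and 2 of 240 in KMS11, and 2 and 8 of 261 in MM.1S. In RPMI8226 the next rises were miR-6722-3p (0.74) and miR-4455 (0.69), and the largest falls miR-16-2-3p (-1.15), miR-378i (-1.11) and miR-378a-3p (-1.06). KMS12BM had rises of miR-762 (1.53) and miR-4281 (1.21) and falls of miR-19b-1-5p (-1.44), miR-4515 (-1.17) and miR-4284 (-0.90). In KMS11 the rises were miR-4701-5p (0.81) and miR-1181 (0.80), and the falls miR-4668-5p (-1.76), miR-7-5p (-1.62) and miR-7-1-3p (-0.96). MM.1S had rises of miR-1246 (1.05) and miR-4701-3p (0.71) and falls of miR-4284 (-1.50), miR-7-5p (-1.34) and miR-15b-3p (-1.27). These counts grew several-fold without scaling, with the spike-ins and with the 75th percentile of all probes.

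The cell lines differed from each other far more than hypoxia differed from normoxia. KMS11 stood out by miR-181a-5p, which was 73.6-fold above the mean of the other 3 lines (log2 difference 6.20, SE 0.14, adjusted p = 1.91e-06, with KMS12BM at the floor), miR-181b-5p (4.22), the oncogenic miR-21-5p (2.75) and miR-125b-5p (2.68). KMS12BM and MM.1S shared a high miR-150-5p, a miRNA of mature lymphocytes, at 5.09 and 3.14 above the mean of the other lines. In KMS11 miR-150-5p was detected on 0 of 2 arrays, at least 7.66-fold lower than the mean of the other lines (adjusted p = 6.66e-06). In RPMI8226 it was detected but low (-3.58). MM.1S had the highest miR-146a-5p, an NF-kappaB-induced miRNA (2.83), and KMS12BM the highest miR-192-5p (3.37, with no detection in RPMI8226 and MM.1S).

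In total 266 of the 286 tested miRNAs passed in at least 1 line contrast (limma, adjusted over all 4 contrasts). In RPMI8226 70 were higher and 95 lower, in KMS12BM 114 and 62, in KMS11 84 and 125, and in MM.1S 92 and 42. RPMI8226 was highest above the others in miR-1246 (2.67), miR-1290 (1.76), miR-4534 (1.58) and miR-5787 (1.47), and miR-195-5p was detected on 0 of its 2 arrays, at least 3.95-fold lower. KMS12BM also had an excess of miR-152 (2.47, with RPMI8226 and MM.1S at the floor) and miR-18b-5p (2.37), and the deficits let-7i-5p (-4.70, detected on 1 of its 2 arrays) and miR-181a-5p, detected on 0 of 2 and at least 7.07-fold lower. The second deficit of KMS11 was miR-551b-3p (-2.98). MM.1S also had an excess of let-7d-5p (2.01) and miR-1973 (1.99), and miR-181c-5p was not detected in it, at least 2.07-fold lower. miR-152, its other deficit, was detected on no array of MM.1S or RPMI8226, so no bound is given. The 24 named contrasts kept their direction and call under every alternative that gave a value. The median and spike-in scalings were not run for them. The counts were less firm and shrank most with the 75th percentile of all probes, which lay at background (a raw signal of 1.16 to 2.34).

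**Figure D3:**
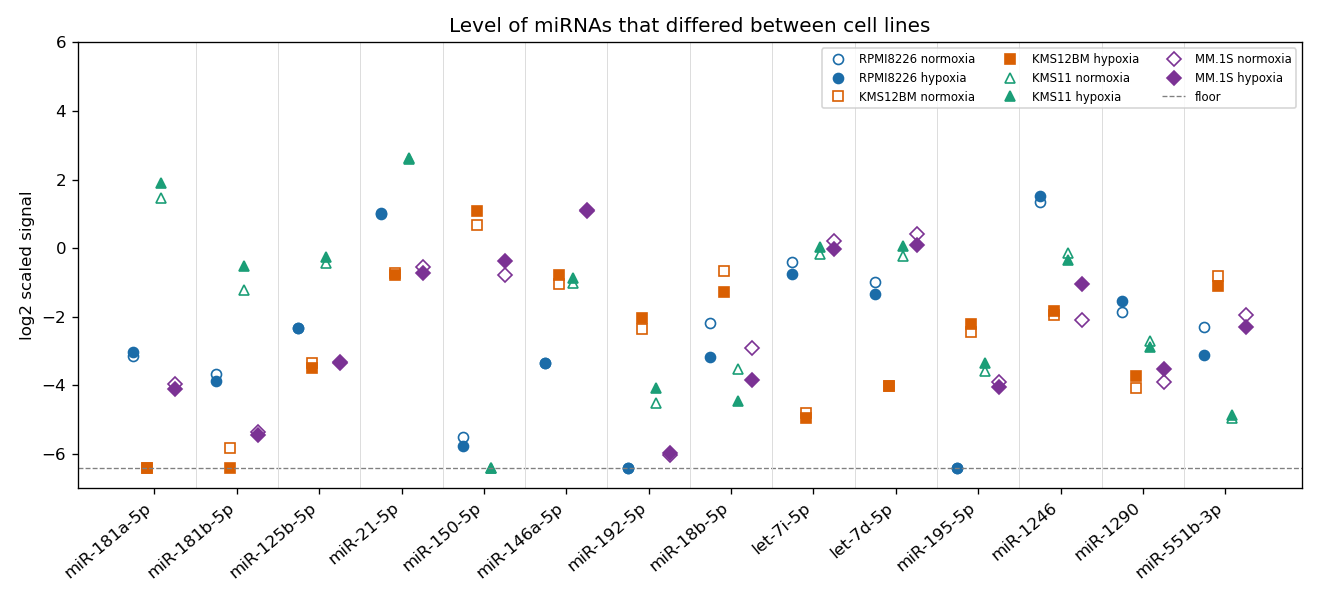
Level of 14 miRNAs (log2 scaled signal, vertical axis) on the 8 arrays, with open symbols for normoxia, filled symbols for hypoxia, a shape and colour per cell line, and a dashed line at the floor of -6.42. miR-181a-5p averaged 1.69 in KMS11 and lay at the floor in KMS12BM, and miR-150-5p averaged 0.88 in KMS12BM and lay at the floor in KMS11.

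The miR-17 family was higher in KMS12BM, where 13 of 13 tested members passed, with a median of 1.82 above the mean of the other lines (8 to 13 members and a median of 1.28 to 1.82 over the scalings). miR-18b-5p (2.37), miR-18a-5p (2.33) and miR-19a-3p (1.88) led. In MM.1S 10 members were lower (median -0.82, with 1 to 12 members and a negative median over the scalings), and in KMS11 8 were lower and miR-25-3p was higher (2 to 9 lower, with a negative median, over the scalings). RPMI8226 had 6 lower members (0 to 6), but its median turned from -0.21 to 0.31 without scaling. The high levels of KMS12BM enter the mean of the others for MM.1S, KMS11 and RPMI8226, and so push their contrasts down. The let-7 family, whose members repress growth-promoting genes, split the lines: 7 of 8 members were lower in KMS12BM, among them let-7d-5p (-3.70) and let-7g-5p (-3.26), while let-7a-5p (0.13) did not pass and miR-98-5p was not detected there. In KMS11 all 8 were higher with the scaling used, with a median of 1.56 (6 to 8 over the scalings), led by let-7c (2.12), and in MM.1S 6 were higher (4 to 6) and 2 lower (0 to 2). No list test was run between lines.

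Of the 11 lymphoid oncogenic miRNAs, 7 were higher (6 to 8 over the scalings) and 3 lower (1 to 3) in KMS11, and 1 was higher (0 to 1) and 7 lower (7 to 8) in KMS12BM. Of the 8 B-lineage miRNAs, MM.1S had 5 higher (5 under each scaling) and 2 lower (0 to 2). miR-142-3p was higher in MM.1S (1.32) and KMS11 (0.83) and lower in RPMI8226 (-1.05) and KMS12BM (-1.10). All 3 tested p53-responsive miRNAs were lower in RPMI8226. miR-34a-5p was detected there on 1 of 2 arrays (-3.12), and miR-192-5p and miR-34b-5p on none. Of the miR-15/16 family 5 of 6 members were lower in RPMI8226 (1 to 5 over the scalings) and 5 higher in KMS11 (0 to 5). The miR-29 family had 3 of 4 members lower in KMS12BM (2 to 3 over the scalings) and 3 higher in KMS11 (1 to 3), and the miR-30 family 2 of 4 lower in KMS12BM (2 to 4) and 3 higher in KMS11 (1 to 4). Neural entries were higher in KMS12BM (3 of 3, 0 to 3 over the scalings) and lower in RPMI8226 (3 of 3, 2 to 3 over the scalings). The GC-rich entries, the sign of RNA or labelling quality, moved with the lines as well: 14 of 19 were higher in RPMI8226 and 15 of 19 lower in KMS11, with medians of 0.55 and -0.83 and the same signs under each scaling (3 to 17 higher in RPMI8226, 7 to 15 lower in KMS11).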

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

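Extremes were searched among the detection and signal values of the arrays and the levels and differences of the named miRNAs. A value counted as extreme when its Dixon ratio among 4 lines passed the critical value, and 8 of 123 groups of values held such a value, where about 1 in 20 would by chance. Each was kept. In levels, they were miR-135a-3p under normoxia in KMS11 (-6.26, near the floor), miR-3960 under hypoxia in KMS11 (0.76) and miR-19a-3p under hypoxia in KMS12BM (2.36). In the differences between hypoxia and normoxia, they were miR-3940-5p in KMS11 (0.74), miR-29b-3p in RPMI8226 (-0.42), miR-155-5p in RPMI8226 (0.81), miR-4281 in KMS12BM (1.21) and miR-19b-1-5p in KMS12BM (-1.44). No spot was saturated, and 2.40% to 3.16% of the spots per array were outliers.

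miRNAs detected on 1 to 3 arrays were left out of the main tests and entered only alternatives with other detection filters. Of 105 such miRNAs, 55 were detected on hypoxia arrays alone and 8 on normoxia arrays alone. Among the 55, 7 were detected on 3 hypoxia arrays (RPMI8226, KMS12BM and MM.1S) and no normoxia array: miR-1185-1-3p, miR-4327, miR-4478, miR-4651, miR-6086, miR-664b-5p and miR-765. With detection on at least 1 array as the filter, miR-4651 was the only 1 of these 7 called higher (limma). The counts of 55 and 8 were not tested. The hypoxia arrays were brighter before scaling, and these 3 lines were those with more detected miRNAs under hypoxia.

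The tests in the next paragraph were chosen only after the brighter hypoxia arrays had been seen.

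Before scaling, the hypoxia arrays were brighter by 0.49 at the 75th percentile of the common probes. Stronger labelling or scanning in the hypoxia row would raise the labelling spike-ins too, but these differed by -0.10 on the log2 scale, below the step in 4 of 4 lines, which argues against it. More RNA of every kind would raise the brightest miRNAs as well, yet the 13 brightest had a median difference of 0.026 (SD 0.36), which argues against that. The share of the 10 brightest entries fell by 3.63 percentage points, as a change in composition would give. With the log2 summed signal changed by 0.04 and the 75th percentile by 0.49, such a fall nearly had to follow. It restates the pattern and does not test a change in composition. Whether the composition changed, and if so in the cells or in the RNA preparation, stays open, since slide row and condition coincide. An RNA input measured per culture with hypoxia arrays in both slide rows would help to tell.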

How the results depend on the processing

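Most alternatives changed 1 step and kept the rest, while normexp and the authors' table changed several at once, and the cause of a shift was not tested. The 75th percentile of all probes lay at background, so that scaling divides by noise. Of the 25 called miRNAs named for hypoxia, the number that stayed the same was 25 with 0.5 times the floor, 24 with robust eBayes, 23 with the median scaling, 22 with the brightest probe, 20 with 2 times the floor, 20 with the trend and 18 with the total gene signal of the files. It was 17 with the mean of log2 values, 16 with detection on at least 1 array, 16 with the files' own detection flag, 11 with normexp and 10 each with quantile scaling, no scaling and the spike-ins. It was 1 with the 75th percentile of all probes and 0 with the authors' table and without the block. It was 18 without RPMI8226, 7 without KMS12BM, 12 without KMS11 and 8 without MM.1S, and 19 of the 19 detected on all 8 arrays. The named line contrasts kept direction and call under every alternative run for them, which left out the median and spike-in scalings. The median and spike-in scalings were chosen after seeing the data. Removal of saturated spots and a slide block were not run, as the files gave them nothing to change.

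The hypoxia counts of 9 higher and 46 lower became 2 and 0 with the 75th percentile of all probes, 3 and 9 with quantile scaling, 83 and 1 with none, and 153 and 1 with the spike-ins. They became 5 and 25 with the total gene signal, 0 and 0 with the authors' table, 3 and 28 with detection on at least 1 array, and 0 and 0 without the cell line as a block. The lower count was 14 with normexp, and the higher count was 3 with the files' own detection flag and 15 with the median scaling. Leaving out 1 line gave 1 (without KMS12BM or MM.1S) to 4 (without RPMI8226) higher, and 6 (without KMS12BM) to 36 (without RPMI8226) lower.

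A sign is called reversed where it turned and the miRNA passed before or after. Signs reversed with the spike-ins for miR-6085 (0.013), miR-19a-3p (0.015), miR-20b-5p (0.025), miR-20a-5p (0.026), miR-142-3p (0.15) and miR-487b (0.13), all of which fell with the scaling used. They also reversed there for miRNAs that had not passed: miR-27b-3p (0.40), let-7g-5p (0.43), let-7a-5p (0.45), miR-16-5p (0.45), miR-23b-3p (0.46), miR-27a-3p (0.48), miR-24-3p (0.56), miR-30e-5p (0.45), miR-30c-5p (0.49), miR-9-5p (0.40) and miR-9-3p (0.42). miR-142-3p and miR-487b reversed too with the 75th percentile of all probes (0.080 and 0.061) and without scaling (0.051 and 0.031). Of the 75 named miRNAs, a further 26 turned sign without scaling, 25 with the 75th percentile of all probes and 15 with the spike-ins, all to positive and none past the threshold before or after. With each other alternative 0 to 7 did.

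Of the list tests 3 passed (the miR-17 family, the hypoxia-lowered list and the GC-rich list), against 1 with quantile scaling, 1 with detection on at least 1 array, 1 without the block, 0 with an estimated correlation and 0 with fry. Leaving out 1 line gave 1 (without RPMI8226 or MM.1S) to 3 (without KMS12BM or KMS11). The miR-17 family lost its call with an estimated correlation (adjusted p = 0.872 with an estimated correlation) and with fry (adjusted p = 0.0539). The hypoxia-lowered list lost its call with quantile scaling (adjusted p = 0.179), normexp (0.145), the mean of log2 values (0.0742), the authors' table (0.129), detection on all 8 arrays (0.211) or on at least 1 (0.0751), 2 times the floor (0.111), no block (0.207), an estimated correlation (0.872) and fry (0.0612), and ranged from 0.00894 (without KMS12BM) to 0.0887 (without RPMI8226) when a line was left out. The GC-rich list lost its call with quantile scaling (0.0547), the total gene signal (0.0597), detection on at least 1 array (0.0751), no block (0.0694), an estimated correlation (0.727) and fry (0.246), and ranged from 0.00894 (without KMS12BM) to 0.0806 (without RPMI8226) when a line was left out. The hypoxia-raised list gained a call with the 75th percentile of all probes (0.0216) and without scaling (0.0241).

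Across the line contrasts there were 360 calls of miRNAs higher in one cell line and 324 calls of miRNAs lower in one cell line. With the 75th percentile of all probes these became 125 (31 in RPMI8226, 17 in KMS12BM, 39 in KMS11 and 38 in MM.1S) and 135 (among them 35 in RPMI8226, 38 in KMS11 and 10 in MM.1S). The 114 miRNAs higher in KMS12BM became 71 with quantile scaling, 52 without scaling, 67 with normexp and 51 with the authors' table, and ranged from 74 (without its own normoxia array) to 116 when 1 array was left out. Without scaling there were 107 miRNAs higher in RPMI8226 in place of 70 and 49 miRNAs lower in RPMI8226 in place of 95. The 92 miRNAs higher in MM.1S became 57 with normexp, 60 with the authors' table and 60 with detection on all 8 arrays, and the 42 miRNAs lower in MM.1S became 64 with detection on at least 1. The 125 miRNAs lower in KMS11 became 69 with the authors' table.

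Counted by difference per cell line, those over 2-fold numbered 24, against 242 with the 75th percentile of all probes, 87 without scaling and 106 with the spike-ins. Opposite differences over 2-fold in separate lines were seen for 0 miRNAs, and for 3 with the 75th percentile of all probes. The mean number of detected miRNAs kept its direction with the files' own detection flag (difference 33). The difference in KMS11 turned from -19 to 1, so that 4 of 4 lines were higher (exact sign-flip permutation p = 0.125). Detection here means signal over background on the array, so an undetected miRNA is not shown to be absent.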

Other observations

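The differences under hypoxia resembled each other between most cell lines. Across the 286 tested miRNAs, the per-line differences correlated most between KMS11 and MM.1S (r = 0.59) and KMS12BM and MM.1S (r = 0.55) and least between RPMI8226 and KMS11 (r = 0.13). The 13 brightest miRNAs had a median difference of -0.46 with scaling and 0.03 without, and the 103 dimmest -0.12 and 0.32. In lists of the same size and signal level drawn at random, 0.47% had a median at or below that of the hypoxia-lowered list, and 77.1% and 99.8% at or below those of the hypoxia-raised and GC-rich lists.

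Of the tests here, those of the passenger strands, of the family under other scalings, of the normoxia level of miR-210 and of the neighbouring genes and hairpin arms were chosen only after the results were seen, and the level-matched lists, the splits and the weaker hypoxia of RPMI8226 were set earlier.

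The lower miR-17 family was weighed against technical sources. It kept a negative median with called members under 3 of 6 other scalings (quantile -0.42, normexp -0.32, median -0.50) and had 0 called members and a median of -0.07, 0.03 and -0.04 without scaling, with the spike-ins and with the 75th percentile of all probes, so the part of the scaling factor in its fall stays open, while its place below the median of all tested miRNAs (-0.43 without scaling, -0.44 with) is left nearly alike by any single factor per array. Of 10000 lists matched for signal level, 0% reached its median of -0.56, and the median of their medians was -0.16. This argues against a shift that follows level alone. The share of 0% overstates how rare such a median is, since the drawn lists held unrelated miRNAs while the family had an estimated correlation of 0.668. The match was also loose for the brightest members, as miRNAs with a level over 2 had a median of -0.46 and those at 0 to 2 of -0.20. Cross-hybridisation among the near-identical guide strands would spare the passenger strands. Of these, miR-17-3p (-0.82) and miR-20a-3p (-0.73, detected on 5 of 8 arrays) fell, while miR-19b-1-5p (-0.40, limma adjusted p = 0.30) did not pass. Their mean was -0.65. As miR-19b-1-5p lay at the floor on both arrays of RPMI8226 and MM.1S, its result says little, and sharing of signal stays open. A shift in RNA or labelling quality stays open too, since the GC-rich list stood above the other miRNAs under hypoxia (camera adjusted p = 0.0282, adjusted p = 0.727 with an estimated correlation) and above 99.8% of level-matched lists, and small RNA sequencing of the same cultures would help to separate these.

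Other groupings of the arrays were fitted in the same way. Among the 8 that part all 4 pairs, 1 reached the number of 55 calls, the real one itself, and the highest other number was 0. For the miR-17 family 1 of 8 reached the real mean of 0.604 (absolute value), again the real one, with 0.382 as the highest other. The others exchange the conditions in 1 or 2 lines. A response shared by the lines then enters the residual spread and shrinks the tested difference. Few calls in these groupings would thus follow from the response itself, and their 0 calls do not show what chance alone gives. A further 24 groupings that part 2 pairs gave 0 calls and a family mean of up to 0.730, and 3 could not be fitted. The 8 splits are too few for a share under 0.05.

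If the RPMI8226 culture, with its smaller miR-210 difference, were less hypoxic, other miRNAs would differ less as well, and the median ratio of RPMI8226 to the other lines was 0.802 over 39 miRNAs (95% bootstrap interval 0.408 to 1.04), which leaves this undecided, with a ratio of 0.494 for miR-210. The same ratio was 0.683 in KMS12BM (6 miRNAs), 0.637 in KMS11 (16) and 1.21 in MM.1S (7). Each ratio covers a different set of miRNAs, those called from the remaining lines, so the ratios are not directly comparable. Those of KMS12BM and KMS11 lay within the interval of RPMI8226. The order of the lines is thus not established and does not decide whether the RPMI8226 culture was less hypoxic. A high miR-210 level under normoxia would shrink the miR-210 difference. This level was -1.51 in RPMI8226 against -0.85, -1.46 and -2.28 in KMS12BM, KMS11 and MM.1S, which argues against a high level as the source. RPMI8226 had the smallest miR-210 difference in 8 of 9 settings, while with the 75th percentile of all probes, which lay at background, KMS11 did (1.63). Replicate cultures per line with a second hypoxia marker would settle whether the response of this line is weaker.

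Transcripts that carry several miRNAs gave a further prediction: neighbouring genes should differ alike. Pairs of tested miRNAs whose genes lie within 10 kb differed from each other by 0.222 on average, against 0.401 after permutation (46 pairs, 47 miRNAs, permutation adjusted p = 0.00024). Outside the miR-17 family the gap was 0.229 against 0.297 (25 pairs, permutation adjusted p = 0.0383). The arms of 1 hairpin differed by 0.193 against 0.321 (15 pairs, permutation adjusted p = 0.00415). Similar sequences within a cluster might share signal and give the same closeness, so the values of 0.222 and 0.229 do not separate shared transcription from it.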
